A study of Mus musculus with 24 samples.

How the data were processed

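Total RNA was extracted with Trizol from hearts of 90-day-old mice of 4 genotypes, 6 biological replicates each, and its quality was checked on a Bioanalyzer. Biotin-labelled cRNA was made from 5 micrograms of RNA and hybridised to Affymetrix arrays. The submitters name RMA as their processing tool, and its version is not given in the sources used here. The deposited values are in the unit ratio, on a linear scale. They centre near 1 in the non-transgenic arrays, though the log2 mean of some probe sets lay lower there (-0.41 for Neat1). Array medians of log2 values lay between -0.05 and 0.09. The step that divided the values by the control level, and the linear scale, were read from the values and are not stated. A ratio holds no signal level, so dim probe sets could not be told from bright ones and no filter on brightness was applied.

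Of 45101 probe sets in the table, 64 Affymetrix controls were left out and 45037 were tested. Of these 34945 had 1 gene symbol (18193 genes), 932 had several and 9160 had none in the annotation used. Symbols were updated through Entrez identifiers for 18032 genes. No coordinates are given, since the values carry no genome build. Log2 of the ratio was taken first, because the values were linear where log2 values had been assumed in the plan. All 24 arrays were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per genotype and the default empirical Bayes step. Each p was adjusted by the Benjamini-Hochberg method over the probe sets of that comparison, and a probe set was called at an adjusted p under 0.05. Changes are given as log2 ± SE of the fitted difference, and "rose" or "fell" is used of what was called. The median SE was 0.0992. The number of arrays sets this precision. The fit shared 1 spread per probe set over the 4 genotypes. The mean SD between replicates was, however, 0.143 in NTG, 0.155 in AC5, 0.221 in GLY and 0.192 in ARG. On average the SE is therefore too small for ARG against GLY and too large for AC5 against NTG. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

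Before the data were examined, these were fixed: the 6 pairwise comparisons, their test, 33 gene lists (787 members, 710 of them matched), the alternatives apart from 6 added ones, and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 33 lists of a comparison. Camera asks whether the genes of a list move more in 1 direction than other genes, and fry whether they move 1 way on balance. The plan took, for each gene, the probe set with the highest mean. Because a mean ratio favours genes that rose, this was replaced after the data were seen by a rule without the values (probe set suffix, then lowest number), also in the alternative with 1 probe set per gene. The highest mean ratio, planned as the main choice for lists, was then added as an alternative. By the rule, genes were named in each main comparison as the 8 largest rises and 8 largest falls among called probe sets whose groups did not overlap. The rule also took the called member of each list with the largest rise and the largest fall, and Adcy5 and Myh6 in any case. Another gene of that rule is not analysed here. In the comparisons of ARG and of GLY with AC5, 4 rises and 4 falls were taken. The rule named 52 genes in ARG against NTG, 40 in GLY against NTG, 22 in AC5 against NTG and 39 in ARG against GLY, of which those that rest on single arrays are partly left out of the text.

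Further list members (19, 9, 2 and 10 in ARG, GLY and AC5 against NTG and in ARG against GLY) were chosen as examples after their values were seen, and some of them are not printed. Printed ones were, in ARG against NTG, Nppb, Col1a1, Col3a1, Postn, Ccn2, Hadhb, Idh2, Cd68, C1qa, Socs3, Casq2, Hrc, Creld2, Pde4d, Rgs2, Fhl1 and Adcy6. In GLY against NTG they were Hadhb, Idh2, Camk2d, Pde4d, Rgs2, Hspd1 and Bex1, in AC5 against NTG Manf, and in ARG against GLY Col1a2, Postn, Myh7, Socs3, Osmr, Cd14, Hspa5, Creld2 and Acaa2. Of called genes named by the rule with over 1 probe set, all probe sets were called the same way for 11 of 22 in ARG against NTG, 7 of 19 in GLY, 5 of 12 in AC5 and 8 of 15 in ARG against GLY. None had a probe set called the other way.

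Structure among the arrays was checked. Of the 10 ways to split the 6 non-transgenic arrays into 3 and 3, the means of the 3 arrays on each side correlated above 0 only for replicates 1 to 3 against 4 to 6 (r = 0.217 over probe sets, against -0.583 to -0.336 for the others). The labels name no such sets. The set was therefore added as a term and each set was fitted alone, as alternatives chosen after seeing the data. Array weights estimated by limma were under 0.5 for GLY replicate 1 (0.354), GLY replicate 3 (0.312) and ARG replicate 1 (0.478). The comparisons were therefore repeated without these 3 arrays, and with a weight per group (1.479 in NTG, 1.26 in AC5, 0.643 in GLY and 0.834 in ARG). Other alternatives were a trended and robust prior, array weights, fitting only the 2 groups compared, median centring, quantile normalization, 1 probe set per gene, a minimum change of 1.5-fold and leaving out each array in turn.

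The pipeline was tested on simulated data, with noise drawn independently for each probe set at its fitted spread and changes added to 100 probe sets at each size in the ARG arrays. At a log2 change of 0.5 it recovered 74%, and at 1 it recovered 98%, with 12 unchanged probe sets called. A simulated fall of the fatty acid oxidation list was called, and 0 other lists were called by camera. Such noise holds no correlation between genes, so this does not measure false list calls in the real arrays.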

Results

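Gene expression was measured on Affymetrix arrays in hearts of mice at 90 days of age. There were 24 arrays, 6 hearts for each of 4 genotypes. Non-transgenic mice (NTG) were set beside mice with a human transgene expressed in heart muscle cells from the alpha-myosin heavy chain promoter. The transgene encoded AC5, the usual name of type 5 adenylyl cyclase, or 1 of 2 polymorphic forms of the beta1-adrenergic receptor, Gly389 (GLY) or Arg389 (ARG). The values were ratios to the non-transgenic level, near 1 in NTG hearts, so changes in a gene were measured but not how abundant its transcript was. Ratios ranged from 0.0636 to 34.8 over all arrays, and the number of hearts limited the precision. The labels name no batches, but in the NTG values replicates 1 to 3 and replicates 4 to 6 each centred near 1 on their own, as a pair of sets would. Values within replicates 1 to 3 and within replicates 4 to 6 of all genotypes are therefore given beside those over all 6 hearts.

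The first question was how ARG hearts differed from NTG hearts. Ccl8, a chemokine that attracts monocytes, rose by 3.46 ± 0.34 on the log2 scale (SE, n = 6 hearts per genotype, adjusted p = 1.38e-07), an 11-fold rise. Timp1, an inhibitor of matrix metalloproteinases, rose by 2.85 ± 0.26, and Lgals3, the lectin galectin-3 of activated macrophages, rose by 2.75 ± 0.26. Acta1, skeletal alpha-actin, fell by 2.47 ± 0.36, and genes of fatty acid oxidation and of the citric acid cycle fell together. Of 16 macrophage markers 13 rose in the same hearts, with a median change of 0.83, or 0.54 after quantile normalization (camera, adjusted p = 0.053 with an estimated correlation).

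**Figure D1:**
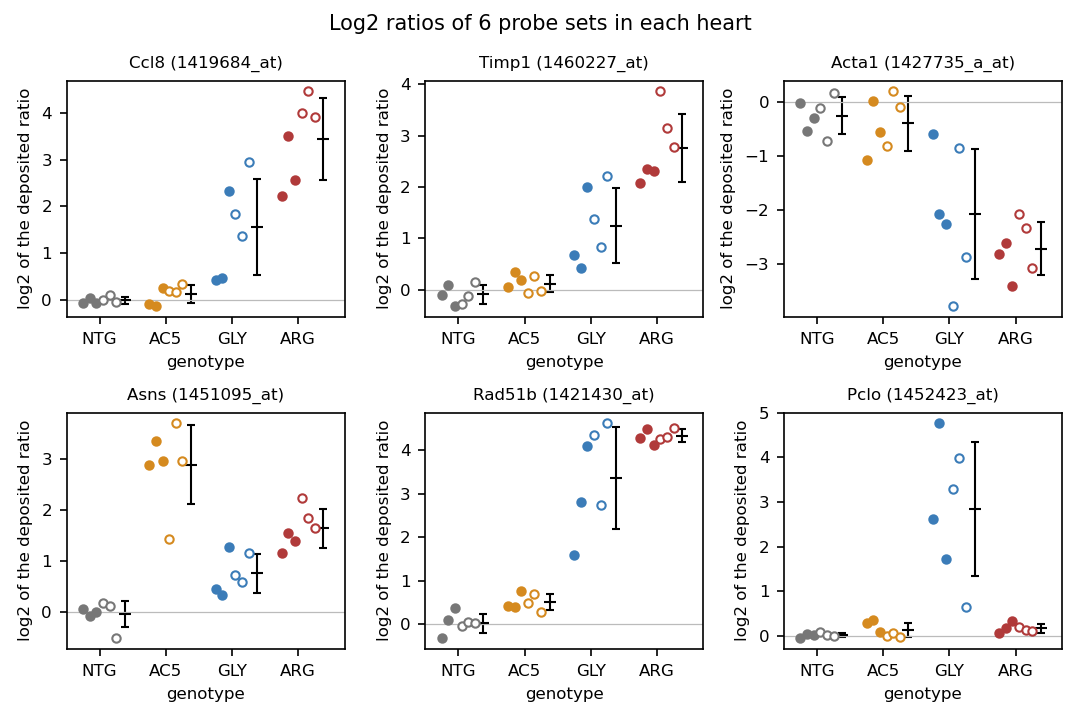
Log2 of the deposited ratio (vertical axes) of 6 probe sets in each heart by genotype (horizontal axes), with filled points for replicates 1 to 3, open points for replicates 4 to 6, and bars for the mean ± SD of 6 hearts. Mean Ccl8 was 3.45 in ARG, 1.56 in GLY, 0.12 in AC5 and -0.01 in NTG, while mean Pclo was 2.84 in GLY and 0.17 in ARG.

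Genes of the extracellular matrix and of inflammation rose in ARG. Of 38 genes of the matrix and fibrosis list, 22 rose and 16 were not called. Adjusted over the list alone, 27 rose. The collagens Col1a1 (1.06 ± 0.22) and Col3a1 (0.93 ± 0.17), the matricellular protein periostin (Postn, 1.08 ± 0.24) and the growth factor Ccn2 (1.13 ± 0.24) were among them. The median change of that list was 0.54, and 0.35 and 0.71 within replicates 1 to 3 and 4 to 6 (camera, adjusted p = 2.58e-20). Its adjusted p was 0.0756 with an estimated correlation. Of 25 genes of inflammation and the acute phase, 14 rose and 11 were not called, with 14 rising when adjusted over the list alone (median 0.43, within sets 0.30 and 0.55, adjusted p = 6.38e-10). That call held with an estimated correlation (adjusted p = 0.0415). Socs3, an inhibitor of cytokine signalling, rose by 1.28 ± 0.15. Serpina3n, an acute phase protease inhibitor, rose by 2.10 ± 0.25, and Cd44, a receptor for hyaluronan, by 2.31 ± 0.22.

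Markers of macrophages moved with these groups. Of 16 such markers 13 rose, the same number adjusted over the list alone, among them Cd68 (0.96 ± 0.19) and the complement gene C1qa (0.77 ± 0.17). Their median was 0.53 within replicates 1 to 3 and 1.09 within replicates 4 to 6 (camera, adjusted p = 2.74e-16, and 0.053 with an estimated correlation). Of 12 fibroblast markers 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.22, within sets 0.22 and 0.26, adjusted p = 0.00545, and 0.218 with an estimated correlation). Mfap5, a protein of microfibrils, rose by 1.09 ± 0.15, and Gsn, the actin-severing protein gelsolin, fell by 0.64 ± 0.14. Of 14 endothelial markers 4 fell, with a median of -0.15 (within sets -0.24 and 0.03, adjusted p = 0.0782, and 0.00669 within replicates 1 to 3). Adipocyte markers fell as a list, with 3 of 10 falling, or 4 adjusted over the list alone (median -0.14, within sets -0.17 and -0.15, adjusted p = 0.0158, and 0.16 with an estimated correlation).

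Genes of mitochondrial fuel use fell in ARG. Of 29 genes of fatty acid oxidation 20 fell and 9 were not called, and 23 fell when adjusted over the list alone. Acot1, an acyl-CoA thioesterase, fell by 1.52 ± 0.18. Hadhb, a subunit of the mitochondrial trifunctional protein, fell by 0.86 ± 0.08 at the probe set tested. Another of its 3 probe sets fell and the remaining 1 rose. The median of that list was -0.54, and -0.52 and -0.56 within the sets (camera, adjusted p = 2.25e-20, and 0.012 with an estimated correlation). Of 16 citric acid cycle genes 9 fell, or 10 adjusted over the list alone (median -0.37, within sets -0.45 and -0.31, adjusted p = 1.74e-08, and 0.0415 with an estimated correlation). Suclg2, a subunit of succinyl-CoA ligase, fell by 0.86 ± 0.15 and Idh2, mitochondrial isocitrate dehydrogenase, by 0.78 ± 0.08 at 1 of 2 probe sets. Of 64 genes of oxidative phosphorylation 12 fell and 1 rose, or 13 and 1 adjusted over the list alone. Their median was -0.09, and -0.06 and -0.12 within the sets (adjusted p = 0.000129, and 0.218 with an estimated correlation). Ndufa10 of the first respiratory complex fell by 0.90 ± 0.08 at 1 of 2 probe sets, while Cox6a1 of cytochrome oxidase rose by 0.43 ± 0.09. Ndufab1, the mitochondrial acyl carrier protein, fell by 1.74 ± 0.20 at 1 of its 5 probe sets.

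Heart muscle genes changed in several groups. Of 19 fetal and hypertrophy genes 7 rose and 2 fell, as they did adjusted over the list alone (median 0.16, within sets 0.17 and 0.28, adjusted p = 0.000727, and 0.0756 with an estimated correlation). The natriuretic peptide genes Nppa (1.2 ± 0.30) and Nppb (0.91 ± 0.16), the LIM domain gene Fhl1 (1.15 ± 0.15, at 1 of 2 probe sets) and the deubiquitinase Uchl1 (2.25 ± 0.29) rose. Acta1, a member of the same list, fell by 2.47 ± 0.36. Of 29 calcium handling genes 7 fell, or 9 adjusted over the list alone (median -0.12, within sets -0.10 and -0.18, adjusted p = 0.00543, and 0.0756 with an estimated correlation). Cacna2d1, a calcium channel subunit, fell by 0.97 ± 0.26 at 2 of 5 probe sets, and the calcium-binding proteins of the sarcoplasmic reticulum Hrc and Casq2 fell by 0.53 ± 0.09 and 0.33 ± 0.07. Of 25 ion channel and gap junction genes 5 fell, as they did adjusted over the list alone (median -0.22, within sets -0.16 and -0.32, adjusted p = 0.000923, and 0.0756 with an estimated correlation). The sodium channel subunit Scn4b fell by 0.91 ± 0.22. Tcap, a protein of the Z disc, fell by 0.81 ± 0.10. The sarcomere list was not called by camera (adjusted p = 0.187) and was called down by fry (adjusted p = 0.038). Tmod4, which caps actin filaments, fell by 1.89 ± 0.23 and the muscle kinase Mylk4 by 1.88 ± 0.18.

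Of 44 genes of beta-adrenergic and cAMP signalling 8 rose and 4 fell, or 8 and 5 adjusted over the list alone, and the list had no common direction (adjusted p = 0.201). Grk5, a kinase that desensitizes receptors, rose by 1.29 ± 0.16. Pde4d, which degrades cAMP, rose by 0.78 ± 0.10 at 1 of 2 probe sets. Rgs2, which restrains G protein signalling, rose by 0.89 ± 0.15 at 3 of 4. Pkia, an inhibitor of protein kinase A, fell by 1.03 ± 0.26, and Adcy6, a cardiac adenylyl cyclase, fell by 0.41 ± 0.11. The change of Adcy5 was 0.04 ± 0.09 (adjusted p = 0.878), and that of Myh6, the gene whose promoter drove the transgenes, was -0.37 ± 0.20 (adjusted p = 0.319).

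Of 29 heat shock and unfolded protein response genes 8 rose and 2 fell, or 9 and 2 adjusted over the list alone (median 0.22, or 0.14 after quantile normalization, within sets 0.24 and 0.37, adjusted p = 0.0008, and 0.218 with an estimated correlation). The endoplasmic reticulum genes Sdf2l1 (1.42 ± 0.20) and Creld2 (1.40 ± 0.21) rose, and the cytosolic cochaperone Dnajb1 fell by 1.47 ± 0.25. Of 23 antioxidant genes 7 rose, or 9 adjusted over the list alone (median 0.15, within sets 0.13 and 0.25, adjusted p = 0.000727, and 0.0728 with an estimated correlation), led by the metallothionein Mt2 (1.84 ± 0.25). The cell cycle list had 1 gene of 26 that rose, Cdc20 (0.34 ± 0.08, at 1 of 3 probe sets), as it did adjusted over the list alone (median 0.09, within sets 0.13 and 0.02, adjusted p = 0.0215, and 0.218 with an estimated correlation). Of 17 circadian genes 2 rose and 6 fell, or 2 and 8 adjusted over the list alone, with Nfil3 rising by 1.49 ± 0.15 and Dbp falling (change -0.84 ± 0.16). That list was not called by camera (adjusted p = 0.0748).

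Several of the largest changes lay outside the lists. Rad51b, a gene of DNA repair, rose by 4.30 ± 0.31 on the log2 scale at the probe set 1421430_at (19.6-fold, adjusted p = 1.22e-09), with its other probe set rising too. Nmrk2, a muscle kinase of NAD synthesis, rose by 1.91 ± 0.30. Bex1, a brain expressed X-linked gene, fell by 2.99 ± 0.31 and Lgi1, a secreted neuronal protein, by 2.82 ± 0.29. Mtm1, the phosphatase myotubularin, fell by 1.76 ± 0.23 at 2 of 3 probe sets, and the noncoding RNA Neat1 by 1.64 ± 0.31 at 1 of 2.

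The remaining lists were called by camera in none of the 4 main comparisons, and their adjusted p in ARG against NTG follows. It was 0.8 for hypertrophic signalling and cardiac transcription factors, glycolysis and glycogen, ubiquitin and atrophy, smooth muscle and pericyte markers, and nerve markers. It was 0.999 for apoptosis, 0.14 for the interferon response, 0.0691 for lymphocytes, 0.838 for red blood cells and skeletal muscle, 0.187 for the atrium, 0.344 for lung and thymus, and 0.323 for sex-linked genes. Some of them were called within a single set. Lung and thymus markers were higher in ARG within replicates 1 to 3 (median 0.11, adjusted p = 0.028). In GLY against NTG atrium markers were higher within replicates 4 to 6 (0.43, 0.00215) and sex-linked genes lower within replicates 1 to 3 (-0.41, 0.0102). Within replicates 1 to 3, glycolysis genes were lower in AC5 than in NTG (-0.15, 0.00248) and atrium markers higher in ARG than in GLY (0.15, 0.032). Single members still changed, such as the kinase inhibitor Cdkn1a (0.48 ± 0.13), the growth arrest gene Gadd45a (-0.93 ± 0.10) and the interferon-induced Ifi27l2a (1.27 ± 0.17).

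Over all 45037 probe sets, limma called 4355 between ARG and NTG, of which 1818 rose and 2537 fell, in 1111 and 1779 genes. Of these, 1316 changed by at least 1.5-fold (592 rose and 724 fell). The count was 4759 with the set as a term, 1302 within replicates 1 to 3 (328 rose and 974 fell) and 2517 within replicates 4 to 6 (1371 rose and 1146 fell), and 749 probe sets were called the same way in both sets. Of the calls within replicates 1 to 3, 98.5% went the same way in replicates 4 to 6. Without GLY replicates 1 and 3 and ARG replicate 1, which had low array weights, 5931 were called. The ARG and NTG values did not overlap at 2751 probe sets, 6.11% of all, against 0.216% by chance. Leaving out any 1 array gave 3490 to 4533 calls, and quantile normalization gave 2400.

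The second question was how GLY hearts differed from NTG hearts. Ccl8 rose by 1.57 ± 0.34 (n = 6 hearts per genotype, adjusted p = 0.0072), Lgals3 by 1.49 ± 0.26 and Timp1 by 1.35 ± 0.26. Fatty acid oxidation and citric acid cycle genes fell as lists at camera's preset correlation (adjusted p = 0.0522 and 0.073 with an estimated correlation). Pclo, a scaffold protein of presynaptic terminals, rose by 2.81 ± 0.38 (7.01-fold, adjusted p = 8.27e-05) at 1 of its 3 probe sets, 1452423_at. Its log2 ratio was 0.64 in GLY replicate 6 and 1.72 to 4.76 in the other GLY hearts. That spread is wider than the SE, which is pooled over genotypes, reflects.

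Of 29 fatty acid oxidation genes 12 fell in GLY, or 16 adjusted over the list alone (median -0.31, within sets -0.26 and -0.27, adjusted p = 7.68e-15). That adjusted p was 0.0522 with an estimated correlation. Acadm, the medium-chain acyl-CoA dehydrogenase, fell by 0.66 ± 0.13. Hadhb fell by 0.60 ± 0.08 at the probe set tested, with another probe set falling and 1 rising. Of 16 citric acid cycle genes 8 fell, or 10 adjusted over the list alone (median -0.30, within sets -0.35 and -0.16, adjusted p = 9.35e-08, and 0.073 with an estimated correlation). Suclg2 fell by 0.91 ± 0.15 and Idh2 by 0.61 ± 0.08 at 1 of 2 probe sets. Pdha1, a subunit of pyruvate dehydrogenase, fell by 0.74 ± 0.16 and Ndufs1 of the first respiratory complex by 0.65 ± 0.13. Ndufab1 fell by 1.59 ± 0.20 at 1 of 5 probe sets. Ghitm, a protein of the inner mitochondrial membrane, fell by 1.28 ± 0.22.

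Of 29 calcium handling genes 4 fell in GLY, or 8 adjusted over the list alone (median -0.11, or -0.07 after quantile normalization, within sets -0.18 and -0.10, adjusted p = 0.0141, and 0.176 with an estimated correlation). Cacna2d1 fell by 1.24 ± 0.26 at 1 of 5 probe sets and Camk2d, a calcium-dependent protein kinase, by 0.58 ± 0.13 at 2 of 7. Of 24 sarcomere genes 1 fell, or 3 adjusted over the list alone (median -0.07, within sets -0.09 and -0.03, adjusted p = 0.0141, and 0.474 with an estimated correlation). The called gene was Nexn, an actin-binding Z disc protein, which fell by 1.12 ± 0.22. Acta1 fell by 1.83 ± 0.36. In the beta-adrenergic and cAMP list 4 genes rose and 4 fell, or 4 and 7 adjusted over the list alone, and camera did not call it (adjusted p = 0.678). Grk5 rose by 0.79 ± 0.16, Pde4d by 0.61 ± 0.10 (at 1 of 2 probe sets) and Rgs2 by 0.74 ± 0.15 (at 3 of 4). Pkia fell by 1.02 ± 0.26 (adjusted p = 0.022), with no call without NTG replicate 1 (0.0605), NTG replicate 6 (0.0519), GLY replicate 1 (0.0642) or GLY replicate 3 (0.0644). Adcy5 changed by -0.13 ± 0.09 (adjusted p = 0.507) and Myh6 by -0.34 ± 0.20 (adjusted p = 0.382), neither of them called.

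Of 29 heat shock and unfolded protein response genes 4 fell in GLY, while 2 rose and 8 fell adjusted over the list alone. Their median was -0.18, with -0.31 within replicates 1 to 3 and 0.01 within replicates 4 to 6 (adjusted p = 0.0141, and 0.623 with an estimated correlation). Hspd1, the mitochondrial chaperonin, fell by 0.93 ± 0.15. The inducible Hspa1b fell by 1.49 ± 0.39 at 2 of 3 probe sets, with an adjusted p of 0.0254 that exceeded 0.05 without NTG replicate 3 (0.0796), NTG replicate 5 (0.0692) or GLY replicate 4 (0.0611). Of 23 antioxidant genes 3 rose, or 5 adjusted over the list alone (median 0.06, within sets 0.10 and 0.12, adjusted p = 0.0141, and 0.298 with an estimated correlation). Of 38 matrix genes 1 rose, Timp1, as it did adjusted over the list alone (median 0.16, within sets 0.11 and 0.18, adjusted p = 0.0363, and 0.725 with an estimated correlation). Macrophage markers, which moved with the matrix genes in ARG, had a median of 0.19 in GLY, with 1 of 16 that rose and 1 that fell. Within replicates 4 to 6 these markers (median 0.25, adjusted p = 8.66e-05) and inflammation genes (0.10, 0.00215) were called higher. Within replicates 1 to 3 endothelial markers (-0.18, 0.042) and oxidative phosphorylation genes (-0.02, 0.0242) were called lower.

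Outside the lists, Rad51b rose in GLY by 3.34 ± 0.31 at 1 of its 2 probe sets. Dct, an enzyme of melanin synthesis, rose by 1.32 ± 0.20 and the keratin gene Krt18 by 1.15 ± 0.20. Lgi1 fell by 2.11 ± 0.29, Mtm1 by 1.81 ± 0.23 at 2 of 3 probe sets, and Bex1 by 1.96 ± 0.31. Smg1, a kinase of nonsense-mediated decay, fell by 1.13 ± 0.18 at 2 of 4.

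The GLY comparison gave 2286 calls by limma, 696 up and 1590 down, in 428 and 1152 genes. Of these 679 changed by at least 1.5-fold (100 rose and 579 fell). The count was 2723 with the set as a term, 2740 within replicates 1 to 3 and 72 within replicates 4 to 6, with 39 called the same way in both. Of the calls within replicates 1 to 3, 79.2% went the same way in replicates 4 to 6. A test of whether the change differed between the sets called 0 probe sets with limma, with 6776 at an unadjusted p under 0.05. GLY and NTG values did not overlap at 1207 probe sets, 2.68% against 0.216% by chance. The count rested on single arrays, with 1355 calls without NTG replicate 3, 1337 without GLY replicate 3 and 3961 without GLY replicate 6. It was 1312 without the 3 arrays of low weight, 1475 with a trended and robust prior, 1247 when only NTG and GLY arrays were fitted, and 633 after quantile normalization.

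The third question was how AC5 hearts differed from NTG hearts. Asns, which makes asparagine, rose by 2.92 ± 0.25 (7.57-fold, n = 6 hearts per genotype, adjusted p = 2.54e-07), and Phgdh, the first enzyme of serine synthesis, rose by 2.33 ± 0.22. Mthfd2, a mitochondrial folate enzyme, rose by 1.57 ± 0.17, Slc7a5, a transporter of large neutral amino acids, by 1.33 ± 0.23, and Aldh18a1, of proline synthesis, by 1.30 ± 0.18. Plcd1, a phospholipase C, rose by 2.06 ± 0.20 at 1 of its 2 probe sets, and the cell adhesion gene Pcdh17 by 1.58 ± 0.15. The mouse Adcy5 probe set changed by 0.41 ± 0.09, with no overlap between the groups but an adjusted p of 0.0813. It was called with array weights or a weight per group (0.00691 in each), with only NTG and AC5 arrays fitted (0.00761), after quantile normalization (0.00795) and without the 3 arrays of low weight (0.0203), though in neither set alone.

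Of 29 heat shock and unfolded protein response genes 1 rose in AC5, or 6 adjusted over the list alone, and 24 were higher (median 0.24, within sets 0.17 and 0.31, adjusted p = 1.57e-10, and 0.0589 with an estimated correlation). The called gene was Dnajb9, a chaperone of the endoplasmic reticulum, which rose by 0.84 ± 0.16. Manf, a protein secreted under stress of that organelle, changed by 0.91 ± 0.21 (adjusted p = 0.0778). It was called without AC5 replicate 1 (0.029) or AC5 replicate 4 (0.0165), and with array weights (0.00998), a weight per group (0.016), quantile normalization (0.00483) or the 3 arrays of low weight left out (0.0414). The Dnajb9 call (adjusted p = 0.0206) was lost without NTG replicate 1 (0.0773), NTG replicate 5 (0.0702), AC5 replicate 2 (0.0754), AC5 replicate 3 (0.051), AC5 replicate 5 (0.0519) or AC5 replicate 6 (0.0616).

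Fatty acid oxidation genes fell as a list, with 1 of 29 falling, or 14 adjusted over the list alone (median -0.22, within sets -0.32 and -0.19, adjusted p = 2.01e-15, and 0.0442 with an estimated correlation). Citric acid cycle genes did too, with 1 of 16 falling, or 4 adjusted over the list alone (median -0.20, within sets -0.31 and -0.09, adjusted p = 3.52e-08, and 0.0589 with an estimated correlation). Oxidative phosphorylation genes had 1 of 64 falling, or 2 adjusted over the list alone (median -0.04, within sets -0.06 and 0.00, adjusted p = 0.0316, and 0.684 with an estimated correlation). Among single genes outside the lists, Bckdha of the branched-chain ketoacid dehydrogenase (-0.62 ± 0.13) and Ldhd, a lactate dehydrogenase (-0.55 ± 0.10), fell. The Bckdha call ended without any 1 of 11 arrays, with an adjusted p of up to 0.154 without AC5 replicate 3, and the Ldhd call without AC5 replicate 3 (0.0538).

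Immediate early and CREB target genes were lower as a list, with 1 of 24 falling adjusted over the list alone (median -0.12, within sets -0.04 and -0.19, adjusted p = 0.0454, and 0.613 with an estimated correlation). Ribosomal protein genes were higher as a list, with 20 of 26 higher and no single call (median 0.08, within sets 0.12 and 0.08, adjusted p = 0.00261, and 0.348 with an estimated correlation). Fibroblast markers were lower, with no single call (median -0.18, within sets -0.17 and -0.17, adjusted p = 0.0469, and 0.613 with an estimated correlation). Endothelial markers were lower as well, with 1 falling adjusted over the list alone (median -0.15, within sets -0.26 and -0.04, adjusted p = 0.039, and 0.613 with an estimated correlation). Within single sets, sarcomere genes were called lower in replicates 1 to 3 (-0.12, adjusted p = 0.0285) and antioxidant genes higher in replicates 4 to 6 (0.05, 0.0348). The ventricular fetal myosin Myh7 rose by 0.94 ± 0.19 (adjusted p = 0.0369). That call ended without any 1 of 9 arrays, with an adjusted p of up to 0.125 without AC5 replicate 2.

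In AC5, limma called 64 probe sets, 31 up and 33 down, in 15 and 28 genes, with 3268 at an unadjusted p under 0.05. Of these 29 changed by at least 1.5-fold (23 rose and 6 fell). The count was 83 with the set as a term and 18 within replicates 1 to 3 (16 rose and 2 fell). Within replicates 4 to 6 limma called 0, with 2512 at an unadjusted p under 0.05. AC5 and NTG values did not overlap at 550 probe sets, 1.22% against 0.216% by chance. Leaving out 1 array gave 26 calls (NTG replicate 1), 29 (NTG replicate 2), 41 (NTG replicate 3), 34 (NTG replicate 5), 26 (NTG replicate 6), 28 (AC5 replicate 2), 22 (AC5 replicate 3) or 37 (AC5 replicate 6). The count was 23 with a trended and robust prior (21 rose and 2 fell) and 188 without the 3 arrays of low weight. It was 299 with only NTG and AC5 arrays fitted, 525 with array weights, 432 with a weight per group and 398 after quantile normalization. NTG and AC5 hearts varied least (mean SD between replicates 0.143 and 0.155, against 0.221 in GLY). The shared spread thus makes the SE of AC5 against NTG too large on average.

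The fourth question, named by the series title, was how the receptor forms differed from each other. Each form was carried by a single group of mice. Its effect cannot be told apart from other differences between these groups, such as the level of the transgene, which was not analysed here. Macrophage, inflammation and stress genes were higher in ARG than in GLY as lists, and so were matrix genes at camera's preset correlation (adjusted p = 0.0526 with an estimated correlation). Ccl9, a chemokine of myeloid cells, was higher by 1.57 ± 0.21 (n = 6 hearts per genotype, adjusted p = 0.00018), Ccl6 by 1.32 ± 0.21 and Ccl8 by 1.89 ± 0.34. Stc2, a secreted stanniocalcin, was lower in every ARG heart than in every GLY heart (change -1.27 ± 0.11, adjusted p = 2.2e-07). Pclo was lower at 1 of 3 probe sets by a change of -2.66 ± 0.38, with means of 0.17 ± 0.09 in ARG and 2.84 ± 1.5 in GLY (SD).

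Of 16 macrophage markers 8 were called higher in ARG than in GLY, and 16 adjusted over the list alone (median 0.66, within sets 0.58 and 0.80, adjusted p = 6.79e-23). That call held with an estimated correlation (adjusted p = 0.0179), and the median was 0.42 after quantile normalization. Ctss, the protease cathepsin S of antigen-presenting cells, rose by 1.33 ± 0.20, and Ms4a6b, a membrane protein of immune cells, by 1.18 ± 0.14. Of 25 inflammation genes 8 rose, while 13 rose and 1 fell adjusted over the list alone (median 0.31, within sets 0.24 and 0.45, adjusted p = 4.23e-12, and 0.0179 with an estimated correlation). Cd14, a coreceptor for endotoxin, rose by 0.92 ± 0.15, Osmr, the oncostatin M receptor, by 0.94 ± 0.14 (at 1 of 3 probe sets) and Socs3 by 0.98 ± 0.15. Of 38 matrix genes 13 rose, or 22 adjusted over the list alone (median 0.39, within sets 0.30 and 0.52, adjusted p = 7.33e-24, and 0.0526 with an estimated correlation). Timp1 rose by 1.5 ± 0.26, Ccn2 by 1.2 ± 0.24, Postn by 1.18 ± 0.24 and Col1a2 by 0.73 ± 0.15 at 1 of 3 probe sets. Fibroblast markers had 2 of 12 that rose, or 5 adjusted over the list alone (median 0.21, within sets 0.29 and 0.17, adjusted p = 0.000502, and 0.131 with an estimated correlation).

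Of 29 heat shock and unfolded protein response genes 9 rose and 1 fell, or 18 and 1 adjusted over the list alone (median 0.43, within sets 0.55 and 0.43, adjusted p = 1.31e-16, and 0.0179 with an estimated correlation). Creld2 rose by 0.99 ± 0.21 and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.68 ± 0.14. Hspa1b had the largest rise of this list (1.60 ± 0.39, at 1 of 3 probe sets), from a GLY mean of -1.57 to 0.03 in ARG. Its adjusted p of 0.0341 exceeded 0.05 without any 1 of 9 arrays, with 0.0777 without GLY replicate 4 and 0.0693 without ARG replicate 2. Of 19 fetal and hypertrophy genes 5 rose, or 10 adjusted over the list alone (median 0.32, within sets 0.16 and 0.22, adjusted p = 1.86e-05, and 0.0438 with an estimated correlation). After quantile normalization the median of that list was 0.13. Myh7 rose by 1.03 ± 0.19.

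Fatty acid oxidation genes were lower in ARG than in GLY at the preset correlation, while the citric acid cycle list (median -0.06, adjusted p = 0.185) and the glycolysis list (adjusted p = 0.578) were not called. Within replicates 4 to 6 the citric acid cycle list was lower (median -0.12, adjusted p = 0.000956), as was calcium handling (-0.09, 0.0264), and within replicates 1 to 3 the sarcomere list was higher (0.06, 0.0468). Of 29 fatty acid oxidation genes 5 fell, or 13 adjusted over the list alone (median -0.23, within sets -0.14 and -0.24, adjusted p = 2.81e-06, and 0.131 with an estimated correlation). Acot1 fell by 1.04 ± 0.18 and Acaa2, a mitochondrial thiolase, by 0.44 ± 0.08. Of 64 oxidative phosphorylation genes 1 fell, Ndufa10 (-0.39 ± 0.08, at 1 of 2 probe sets), as it did adjusted over the list alone (median -0.07, or -0.04 after quantile normalization, within sets -0.05 and -0.11, adjusted p = 0.00581, and 0.501 with an estimated correlation). Of 25 ion channel genes 1 fell, or 3 adjusted over the list alone (median -0.16, within sets -0.09 and -0.20, adjusted p = 0.00418, and 0.131 with an estimated correlation). Of 44 beta-adrenergic and cAMP genes 1 rose, while 8 rose and 2 fell adjusted over the list alone. Their median was 0.08, or 0.04 after quantile normalization, and 0.08 and -0.01 within the sets (adjusted p = 0.00822, and 0.276 with an estimated correlation). The called gene was Pde3b, a phosphodiesterase, which rose by 0.63 ± 0.14. The cell cycle list had 1 of 26 that rose, or 2 adjusted over the list alone (median 0.09, within sets 0.11 and 0.07, adjusted p = 0.00148, and 0.131 with an estimated correlation). Outside these lists, Zbtb16, a zinc finger transcription factor, rose by 1.49 ± 0.22 and the elongation factor Ell2 by 1.2 ± 0.16 at 1 of 2 probe sets. Inmt, a methyltransferase, fell by 1.07 ± 0.17 and Mylk4 by 0.92 ± 0.18. Klf2, a transcription factor of endothelium and a member of the immediate early and CREB target list, fell by 0.76 ± 0.15. Adcy5 changed by 0.17 ± 0.09 (adjusted p = 0.44) and Myh6 by -0.03 ± 0.20 (adjusted p = 0.965), with no call.

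Between ARG and GLY limma called 678 probe sets, 357 higher and 321 lower in ARG, in 249 and 242 genes, and 275 of them differed by at least 1.5-fold (210 higher and 65 lower). The count was 880 with the set as a term, 182 within replicates 1 to 3 (104 higher and 78 lower) and 192 within replicates 4 to 6 (162 higher and 30 lower), with 23 called the same way in both. ARG and GLY values did not overlap at 357 probe sets, 0.793% against 0.216% by chance, and 687 were called without the 3 arrays of low weight. The count moved to 382 without GLY replicate 1, 422 without GLY replicate 5, 1781 without GLY replicate 6, 1041 without ARG replicate 1, 444 without ARG replicate 2 and 400 without ARG replicate 4. It was 95 when only ARG and GLY arrays were fitted, 275 with a weight per group and 58 after quantile normalization. GLY and ARG hearts varied most (mean SD between replicates 0.221 and 0.192, against 0.143 in NTG). The spread shared over 4 genotypes thus makes the SE and p values of ARG against GLY too small on average. Of 100 splits of these 12 arrays, the real one included, 6 called at least as many, so chance was not excluded. GLY replicate 6 lay towards ARG, and a wrong label or a mix of RNA stayed open for it.

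**Figure D2:**
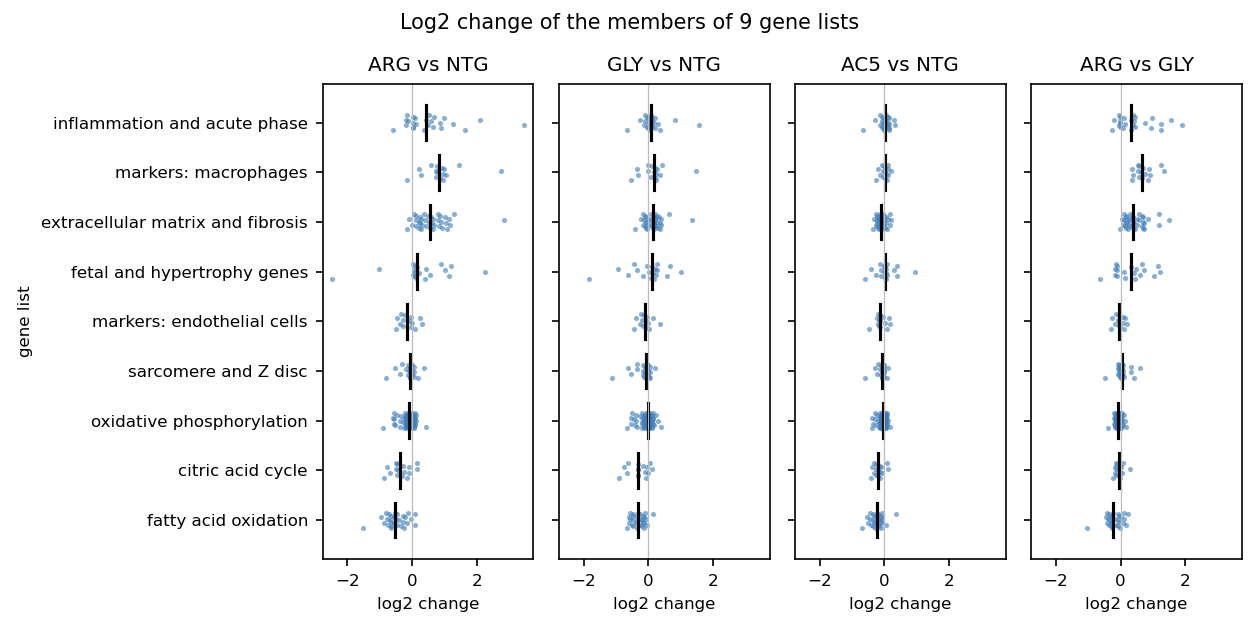
Log2 change (horizontal axes) of each member of 9 gene lists (vertical axis) in 4 comparisons, with 1 point per gene and a black bar for the median. The macrophage marker median was 0.83 in ARG and 0.19 in GLY against NTG, and the fatty acid oxidation median was -0.54 in ARG, -0.31 in GLY and -0.22 in AC5.

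The 3 comparisons with NTG share the same 6 control hearts, which by itself makes their changes correlate. Over probe sets, which are not independent replicates, the ARG and GLY changes correlated at 0.685, against 0.42 for simulated unchanged groups that shared simulated controls. The simulated noise was independent between arrays, so the simulated values cover the shared controls and no other factor common to the genotypes. With the ARG changes from one set and the GLY changes from the other, so that no heart was shared, the correlations were 0.537 and 0.262. The ARG and AC5 changes correlated at 0.528 against 0.419 simulated (0.288 and 0.251 across sets), and the GLY and AC5 changes at 0.579 against 0.42 (0.227 and 0.273). In ARG and GLY 369 probe sets rose and 1071 fell in both, counts that the shared controls can raise and that were not set against unchanged groups. No probe set was called in opposite directions in ARG and GLY. Of the 2915 called in ARG and not in GLY, 444 were also called between ARG and GLY, and of the 846 called in GLY and not in ARG, 34 were.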

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

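The tests of degraded RNA, of a factor that crosses genotypes, of a lower share of muscle cells, and of both explanations for GLY replicate 6 were chosen after the result was seen. The others were written before it.

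GLY hearts gave 2740 calls against NTG within replicates 1 to 3 and 72 within replicates 4 to 6. Degraded RNA was not decided by the control probe sets, since 0 of the 3 arrays of low weight lay below the range of the others in the 5' minus 3' value of actin or GAPDH, though their mean was lower (-0.118 against -0.0517 for actin). A shift or a wider scale of whole arrays stayed open, since the count within replicates 1 to 3 was 42.6 times that within replicates 4 to 6 after median centring but 32 against 71 after quantile normalization, which also widened the NTG arrays. A factor that crosses genotypes may contribute, as the deviations of GLY replicates 1 and 3 correlated with those of ARG replicate 1 at 0.442 and with the next ARG array at 0.213. An effect of the Gly389 receptor present in both sets stays a hypothesis, since 79.2% of the calls of replicates 1 to 3 went the same way in replicates 4 to 6, but their median size was 0.736 in the first set and 0.164 in the other (0.708 and 0.581 for ARG against NTG).

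Macrophage markers were higher in ARG, with a median change of 0.83 against NTG over 16 genes (quartiles 0.70 and 0.97, and 0.54 after quantile normalization), though camera did not call the list with an estimated correlation (adjusted p = 0.053). A lower share of heart muscle cells would raise the markers of every other cell type alike. The endothelial markers, with a median of -0.15 (-0.24 and 0.03 within the sets, -0.07 after quantile normalization) and an upper quartile of 0.00, argue against it as the source. Their median was also lower in GLY (-0.11) and AC5 (-0.15). In ARG the medians were 0.22 for fibroblasts (8 of 12 higher), 0.09 for lymphocytes (10 of 11 higher) and 0 for smooth muscle. All lay below the lower macrophage quartile. More macrophages and other myeloid cells in ARG hearts is a candidate explanation that stays open. On a second list of myeloid genes that shares none with the first, 90.9% of 22 genes were higher in ARG than in GLY (median 0.34, 3 called), led by Ms4a7 (1.06), Clec4n (0.91) and Ptprc (0.82), named after their values were seen, though more transcript per cell and the number of these genes that heart muscle expresses were not tested.

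GLY replicate 6 lay towards ARG, and without it the calls between ARG and GLY numbered 1781 in place of 678. On the probe sets that part the other GLY arrays from ARG, it was nearer to ARG on 73.3%, within the 39.8% to 89.3% that left-out ARG arrays reached and above the 63.8% that left-out GLY arrays reached at most. An ARG heart under a wrong label therefore stays open, by a rule made stricter after these values were seen. No ARG array had high Pclo (0.07 to 0.34). This cannot exclude a swap, since Pclo was named because ARG and GLY arrays did not overlap. The lowest share, 39.8%, was that of ARG replicate 1. A mix of GLY and ARG RNA cannot be told apart from a wrong label. The implied ARG share spread over 71.5 percentage points between quartiles, against 52.8 to 94.9 for left-out ARG arrays. That test replaced an earlier one that argued against a mix, with an implied ARG share of 96.2% by Pclo (0.64 in GLY replicate 6, 1.72 to 4.76 in other GLY) and 30.2% by Stc2 (-0.45, against -1.77 to -1.24 in ARG), and no biological explanation was tested.

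Calls were counted for 100 splits of the 12 arrays of each comparison, the real split included. These were a sample of the possible splits, drawn without regard to the sets or replicate numbers. A split that mixes genotypes keeps their difference in its spread, which lowers its count. For ARG against NTG only the real split reached the real count (4355, with 853 in the highest other). This held for GLY against NTG (2286, highest other 5), AC5 against NTG (64, highest other 29) and ARG against AC5 (2220, highest other 801). For GLY against AC5 2 splits reached it, the real one included (312, highest other 1186). Chance is thus an unlikely source of these counts, but is not excluded. The highest split of GLY and AC5 put replicates 1 to 3 of both genotypes on 1 side, so it follows the sets. With the set as a term that comparison gave 424 calls, and 94 and 16 within the sets. For ARG against GLY 6 splits, the real one included, reached the real count (678), so chance stays open. The highest, with 5928 calls, put GLY replicates 4, 5 and 6 with ARG replicates 2, 4 and 6, and 2 splits exceeded 3 times the real count, which points to a structure of the samples other than the receptor form.

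Single hearts stood far from the other 5 of their group in 25 of 361 groups tested, where chance flags about 1 in 20 groups, or 18. All values are log2 ratios. In AC5 replicate 4, Asns was 1.43 (others 2.88 to 3.7) and Phgdh 0.94 (others 2.26 to 2.87). In GLY replicate 4, Hspa1b was -2.64 (others -1.54 to -1.23) and Hspa1a -2.31 (others -0.95 to -0.65). GLY replicate 3 had Cox6a1 at 0.92 and Hadhb at -0.86. ARG replicate 1 had Pgam1 at 0.24, Dnajb1 at -0.38 and Fign at -1.40. ARG replicate 4 had Scn4b at -1.62, Ifi27l2a at 1.87 and Acaa2 at -0.88. ARG replicate 3 had Egfl7 at -0.93, and ARG replicate 6 had Trim63 at -0.17 and Cd14 at 1.80. Among controls, NTG replicate 4 had Neat1 at -1.60, NTG replicate 5 had Gadd45g at -0.45, NTG replicate 6 had Asns at -0.51 and NTG replicate 3 had Plcd1 at -0.09. In AC5, Xpo6 was -1.03 in replicate 3 and Fos was -2.56 in replicate 5. The GAPDH 5' minus 3' value was 0.09 in NTG replicate 1, -0.06 in AC5 replicate 1 and -0.16 in GLY replicate 2. The mean of the hybridisation spike-in probe sets was 0.92 in NTG replicate 6 (others -0.42 to 0.06).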

How the results depend on the processing

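The set as a term, each set alone, the arrays of low weight left out, a weight per group and, for lists, the probe set with the highest mean ratio (the planned main choice) were alternatives chosen after seeing the data. The rest were planned. No called named gene changed sign under the alternatives run, and no called list of the 4 main comparisons changed direction under the list alternatives. Uncalled genes (Adcy5, Myh6) and uncalled lists did change sign in places. Within replicates 4 to 6 the medians of 3 called lists were not on their side of 0, namely 0.01 for heat shock in GLY against NTG, 0.00 for oxidative phosphorylation in AC5 against NTG, and -0.01 for beta-adrenergic signalling in ARG against GLY. No called list of these comparisons changed the sign of its median after median centring or quantile normalization, though some sizes fell. The set as a term left the calls of the named genes, and of the lists in the 4 main comparisons, as they were. The cause was not tested for the changes below, except where fewer probe sets or arrays entered. A weight per group changes only the spread that the fit allows each genotype. Called probe sets are given in the order ARG, GLY and AC5 against NTG, then ARG against GLY, ARG against AC5 and GLY against AC5.

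Quantile normalization gave 2400, 633, 398, 58, 889 and 165 calls. A minimum change of 1.5-fold gave 1316, 679, 29, 275, 734 and 142. With 1 probe set per gene, hence fewer probe sets, the first 5 comparisons had 2196, 1090, 41, 433 and 1292. Replicates 1 to 3 alone, with fewer arrays, gave 1302, 18, 182, 244 and 94 (without GLY against NTG, where 2740 stayed within 1.5 times), and replicates 4 to 6 alone gave 2517, 72, 0, 192, 1370 and 16. The 0 is by limma, with 2512 at an unadjusted p under 0.05. A trended and robust prior gave 1475 in GLY against NTG, 23 in AC5 against NTG and 207 in GLY against AC5. Fitting only the 2 groups gave 1247 in GLY against NTG, 299 in AC5 against NTG, 95 in ARG against GLY and 126 in GLY against AC5. Array weights gave 525 in AC5 against NTG. A weight per group gave 432 there and 275 in ARG against GLY. Without the arrays of low weight the counts were 1312 in GLY against NTG, 188 in AC5 against NTG and 3540 in ARG against AC5. Leaving out 1 array at a time gave 3490 to 4533, 1337 to 3961, 22 to 90, 382 to 1781, 1588 to 2510 and 157 to 583.

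Lists called with an estimated correlation numbered 3 in ARG, 0 in GLY (7 at the preset correlation, 6 by fry) and 1 in AC5 against NTG, and 4 in ARG against GLY. By fry 3 were called in AC5, and without the arrays of low weight 4 in GLY. When the NTG arrays were divided between the comparisons, the correlations of changes ranged over 10 splits from 0.466 to 0.687 (ARG and GLY), 0.232 to 0.48 (ARG and AC5) and 0.225 to 0.471 (GLY and AC5). The ratios already centred near 1 in NTG within each set. Such a split may therefore not give each comparison controls of its own, and these ranges do not decide whether the similarity outlasts separate controls. Of called named genes, 48 of 50 in ARG, 24 of 38 in GLY and 7 of 20 in AC5 against NTG, and 25 of 37 in ARG against GLY kept their call without any 1 array. In every other alternative 28, 4, 0 and 6 of these kept it. These alternatives include replicates 4 to 6 alone, with 0 calls in AC5 and 72 in GLY against NTG. That fixed the 0 for AC5 in advance and limited the 4 for GLY.

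Replicate numbers taken as a block gave 4551, 2574, 71, 735, 2293 and 322. The labels do not say that a number marks a pairing, and over all genotypes the deviations of same-numbered arrays correlated at 0.059 on average, against 0.053 for other numbers of the same set. GLY and ARG arrays of the same number correlated at 0.243 (0.053 to 0.492, 5 of 6 pairs over 0.1, 3 of 6 GLY arrays best with their own number), against 0.08 for other numbers of the same set, so a shared factor by number is not excluded for these genotypes. The planned filters on dim probe sets were not run, for single probe sets or for lists, since ratios hold no signal over background. An Xist term was not run, since Xist spanned under 1 log2 unit.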

Other observations

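The test of amino acid supply and stress genes was written before its result was seen, and the comparisons with AC5 were planned.

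ARG and GLY hearts were also compared with AC5 hearts, which sets the receptor transgenes beside the cyclase transgene. Against AC5, ARG hearts had higher Ccl8 (change 3.33 ± 0.34, n = 6 per genotype, adjusted p = 9.77e-07 by limma), Timp1 (2.63 ± 0.26) and Lgals3 (2.55 ± 0.26), and lower Bex1 (-3.58 ± 0.31) and Acta1 (-2.33 ± 0.36). Of 38 matrix genes 26 rose, or 31 adjusted over the list alone (median 0.63, within sets 0.40 and 0.84, adjusted p = 8.83e-33, and 0.0272 with an estimated correlation). Of 16 macrophage markers 13 rose, or 14 adjusted over the list alone (median 0.82, within sets 0.49 and 1.12, adjusted p = 8.78e-21, and 0.0272 with an estimated correlation). Of 29 fatty acid oxidation genes 12 fell and 2 rose, or 18 and 2 adjusted over the list alone (median -0.26, within sets -0.21 and -0.37, adjusted p = 3.29e-11, and 0.0478 with an estimated correlation). Atrium markers were higher (median 0.32, within sets 0.14 and 0.09, adjusted p = 0.0234, and 0.208 with an estimated correlation). Adipocyte markers were lower (median -0.17, within sets -0.12 and -0.25, adjusted p = 0.00159, and 0.0582 with an estimated correlation), and fibroblast markers higher (median 0.31, adjusted p = 2.78e-06, and 0.0524 with an estimated correlation). There were 2220 calls, 1134 higher and 1086 lower in ARG. With the set as a term 2514 were called, with 244 and 1370 within the sets.

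Against AC5, GLY hearts had lower heat shock and unfolded protein response genes. Of 29 such genes 7 fell, or 18 adjusted over the list alone (median -0.42, within sets -0.36 and -0.49, adjusted p = 2.26e-18, and 0.015 with an estimated correlation). Fos, an immediate early transcription factor, was higher in every GLY heart than in every AC5 heart (change 2.23 ± 0.40, adjusted p = 0.00522), with group means of 0.81 and -1.41. Immediate early and CREB target genes were higher as a list, with 3 of 24 rising, or 6 adjusted over the list alone (median 0.17, within sets 0.19 and 0.15, adjusted p = 0.000389, and 0.372 with an estimated correlation). Asns (-2.13 ± 0.25), Phgdh (-1.90 ± 0.22) and Plcd1 (-2.20 ± 0.20, at 1 of 2 probe sets) were lower in GLY than in AC5. Markers of the atrium (median 0.33, within sets 0.14 and 0.59, adjusted p = 0.0446), of smooth muscle (0.15, within sets 0.27 and 0.06, 0.0446) and of fibroblasts (0.11, within sets -0.03 and 0.26, 0.0484) were higher. None of these was called with an estimated correlation (adjusted p of 0.405, 0.405 and 0.503). Macrophage markers were called only within replicates 4 to 6 (median 0.28, adjusted p = 1.26e-07). How much atrium or other tissue each sample held was not tested. There were 312 calls, 115 higher and 197 lower, and 424 with the set as a term, with 94 and 16 within the sets. Leaving out 1 array gave 205 calls (AC5 replicate 1), 168 (AC5 replicate 2), 207 (AC5 replicate 5), 199 (AC5 replicate 6), 157 (GLY replicate 3) or 583 (GLY replicate 6).

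The genes with the largest rises in AC5 against NTG included Asns, Phgdh, Mthfd2, Slc7a5 and Aldh18a1, which serve amino acid synthesis and transport. A hypothesis is that they belong to a wider response of amino acid supply and tRNA charging genes. On a second list without those genes, 65.8% of 38 genes were higher in AC5 than in NTG, and the list was called up by camera (adjusted p = 3.16e-08, and 0.027 with an estimated correlation). That list also held transcription factors and stress genes, such as Atf5, Cebpb, Nupr1, Ddit4 and Ppp1r15a. It therefore does not test amino acid supply and tRNA charging alone. The median change was 0.10 and 1 gene was called, the transcription factor Atf5 (1.39, adjusted p = 0.0497), named after its value was seen. The response may thus be wider than the named genes, but small in most of them. In ARG the share (65.8%) and the median (0.10) were the same, with 6 genes that rose and 1 that fell, and the list was called too (adjusted p = 0.016, and 0.318 with an estimated correlation). These values do not set AC5 apart from ARG. In GLY 44.7% of its genes were higher (adjusted p = 0.265). Whether AC5 differs from GLY or ARG on this list was not tested.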
